A study of Mus musculus with 8 samples.

How the data were processed

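The series holds RNA sequencing of ribosome-bound RNA and of whole-tissue RNA from the mouse hypothalamus. Translating ribosome affinity purification (TRAP) was used, in which ribosomes carrying a GFP-tagged RpL10a protein are pulled out of a tissue homogenate with anti-GFP antibodies. RNA kept on the beads is the immunoprecipitate (IP), and RNA of the homogenate is the input. Per the labels, 8 libraries were used here, 4 IP and 4 input, each made from 3 pooled mice of both sexes aged 11 to 12 weeks and killed without fasting. All 8 carry 1 genotype, the deletion of Mff driven by Cre at the Agrp locus. Libraries of the control genotype are not analysed here. Groups and replicate numbers were taken from the sample titles.

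The deposited values are estimated counts per gene, summed from transcript estimates and not normalized. Per the submitters' processing notes, Salmon 0.14.1 and the genome build GRCm38.p6 were used. The annotation release, trimming and strand setting are not given in the sources used here. Between 15.3% and 19.2% of the cells of a library were not whole numbers (tolerance 1e-06), which estimated counts allow. Salmon divides reads that fit several transcripts by a model. Genes with near-identical copies, such as the haemoglobin pair Hba-a1 and Hba-a2, ribosomal protein genes with processed copies and mitochondrial genes with nuclear copies, therefore have uncertain counts. Overlapping or antisense genes cannot be separated with certainty either, since no strand setting is stated. Every sample column of the table belonged to 1 of the 8 libraries, and no pair of libraries held identical values. Pairs of replicates differed by far more than sampling noise. The chi-square per degree of freedom over tested genes was 18.7 to 65.7 within input and 49.7 to 350.1 within IP, so all libraries were counted separately. The labels describe each replicate as its own pool of mice.

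Gene symbols and identifiers came from the table itself, which lists 45706 genes. Of its identifiers 98.8% were found in GENCODE release M21, an annotation of GRCm38, which supplied coordinates, gene type, transcript length and GC content. Length and GC content were those of the longest protein-coding transcript, or of the longest transcript where a gene had none. Among tested genes 99.4% had these values. A symbol written in a list under a newer name was matched through RefSeq synonyms to symbols of the table, such as Ccdc109b (for Mcub) and Scn2a1 (for Scn2a).

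Totals ran from 39.9 to 74.6 M estimated counts (M, mega) per library. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM factors, and IP was compared with input by the quasi-likelihood test with no covariate. P-values were adjusted over the 17000 tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. A second count required a 2-fold change. Positive log2 fold changes mean a higher level in IP. Their standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. CPM are counts per M counts of a library, TMM-scaled and given as mean ± SD over the 4 libraries of a fraction. Counts are relative to the library, so a fold change compares shares of RNA and not amounts per cell.

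The comparison, the 28 gene lists and the rule for named genes were set before the data were examined. The rule takes Mff and Agrp. It takes the 14 genes with the largest change in each direction among genes past the threshold with a mean of at least 10 CPM, no overlap between the fractions and a symbol other than that of a predicted gene. From each list it takes the 2 members with the smallest p in each direction, and all members of the lists of AgRP neuron markers, mitochondrial fission and fusion genes and mitochondrial calcium handling genes may be named. Genes outside the rule are named as chosen after their values were seen. Values of a few list members are not reported, though the members stay in the list counts and tests. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 28 lists. Camera with a correlation estimated from these libraries is given beside each call. That version also refers its statistic to the few residual degrees of freedom of the libraries. Its p can therefore rise without a stronger correlation. Camera asks whether a list moved relative to the other genes. Fry, which tests whether a list's genes move on balance one way without that comparison, and camera on ranks were alternatives. Calls by fry therefore answer a different question. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

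Shares of counts and the levels of Mff and Agrp were compared by 2-sided exact permutation tests. The 70 arrangements of 8 libraries into 4 and 4 allow no p below 0.0286. Shares were adjusted over the 5 compared.

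The procedure was tested on simulated data for the comparison of IP with input, drawn from the mean levels, depths and dispersions of these libraries with 50 genes changed at each size. The test recovered 44% of genes changed 1.5-fold, 68% at 2-fold, 94% at 4-fold and 100% at 8-fold, and 4.97% of its calls among 16497 tested genes were false. The simulation gave both fractions the same spread, which the real libraries do not have. Camera called a simulated list of 20 genes shifted 2-fold and 0 of 20 unchanged lists. The simulated genes were drawn independently, so this does not test the preset correlation. Real lists can be correlated, with an estimate of 0.712 for cytosolic ribosomal protein genes. A simulated trend with transcript length produced 3616 calls, and 11 remained with length and GC offsets.

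Alternatives were RLE, upper quartile and no scaling factors, other gene filters, DESeq2 1.42.0, limma-voom, unrounded counts, libraries thinned to the smallest total, removal of mitochondrially encoded and erythrocyte genes, the replicate number as a block, per-library lowess offsets on GC content and transcript length (span 0.3), and leaving out each library. Removal of 382 ribosomal RNA features, limma-voom with 1 variance weight per fraction, and the offsets applied to the gene lists were chosen after seeing the data. These features are genes annotated as ribosomal RNA or as mitochondrial ribosomal or transfer RNA. Genes thought to take ribosomal RNA reads, such as Lars2, Yam1 and Gm26917, were added to them by name after seeing the data.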

Results

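AgRP neurons are cells of the hypothalamic arcuate nucleus that promote feeding and release AgRP, neuropeptide Y and GABA. Mff encodes mitochondrial fission factor, a receptor on the outer mitochondrial membrane that recruits the fission protein DRP1, the product of Dnm1l. The study concerns this factor in mitochondrial calcium handling and activity of AgRP neurons. The libraries analysed here come from mice with Mff deleted in AgRP neurons, in which the same Cre activates a GFP-tagged ribosomal protein. They comprise 4 ribosome immunoprecipitates (IP) and 4 inputs of the same kind of tissue, and each library is a pool of 3 mice. The comparison they allow is that of ribosome-bound RNA with input RNA within the knockout. The effect of the deletion was not measured, because libraries of the control genotype are not analysed here. Input libraries held 58.3, 74.6, 44.1 and 45.3 M estimated counts (M, mega) and IP libraries 55.3, 50.3, 64.8 and 39.9 M. Between 23120 and 23657 genes had a count above 0 in an input library, and between 19191 and 19617 in an IP library.

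Mff, the targeted gene (ENSMUSG00000026150, chromosome 1, 82724890 to 82752394, plus strand, GRCm38), was detected in all 8 libraries. Its level in input replicates 1 to 4 was 128.8, 122.4, 131.9 and 112.2 CPM, and in IP replicates 1 to 4 it was 64.0, 71.2, 68.6 and 69.7 CPM. Mff was lower in IP by a log2 fold change of -0.86 ± 0.07 (SE, n = 4 libraries per fraction), with an adjusted p of 3.06e-06 in edgeR's quasi-likelihood test. On the log2 CPM scale the means were 6.95 ± 0.10 in input and 6.09 ± 0.07 in IP (SD, n = 4), with an exact permutation p of 0.0286, the smallest that 70 arrangements can give. Reads from parts of the gene outside the deleted exons still count, and input holds Mff RNA of every cell type in the tissue. These levels therefore do not check the deletion.

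RNA of AgRP neurons was strongly enriched in the IP fraction. Agrp itself (ENSMUSG00000005705, chromosome 8, 105566698 to 105637393, minus strand) rose from 3.35 ± 0.74 CPM in input to 843 ± 170 CPM in IP (SD, n = 4), a 252-fold difference. Its log2 fold change was 7.98 ± 0.20 (SE), its adjusted p 5.51e-10 and its exact permutation p 0.0286 (n = 4 per fraction). Npy, the gene of neuropeptide Y, rose 141-fold, from 13.8 ± 0.87 to 1943 ± 450 CPM. Among genes with a mean of at least 10 CPM, separate fractions and a symbol other than that of a predicted gene, the next largest increases were those of Serpina3n, a serine protease inhibitor, with a log2 fold change of 5.46 ± 0.11, Cited1, a transcriptional coactivator, with 5.10 ± 0.11, and Tbx3os2 with 4.93 ± 0.27. The transcript Tbx3os2 lies on the opposite strand beside Tbx3, a transcription factor gene that was itself higher by 4.41 ± 0.10. RP23-148L8.3 was higher by 4.72 ± 0.27, the extracellular matrix gene Tgfbi by 4.47 ± 0.28, Fam159b by 4.42 ± 0.22 and the nuclear receptor gene Nr5a2 by 4.30 ± 0.17. Npy2r, which encodes a neuropeptide Y receptor, was higher by 4.18 ± 0.10, the melanocortin receptor gene Mc3r by 4.16 ± 0.29, Acvr1c, an activin receptor gene, by 4.15 ± 0.14 and the glypican gene Gpc4 by 4.05 ± 0.15. Each of these 14 genes was higher in all 4 IP libraries than in every input library.

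**Figure D1:**
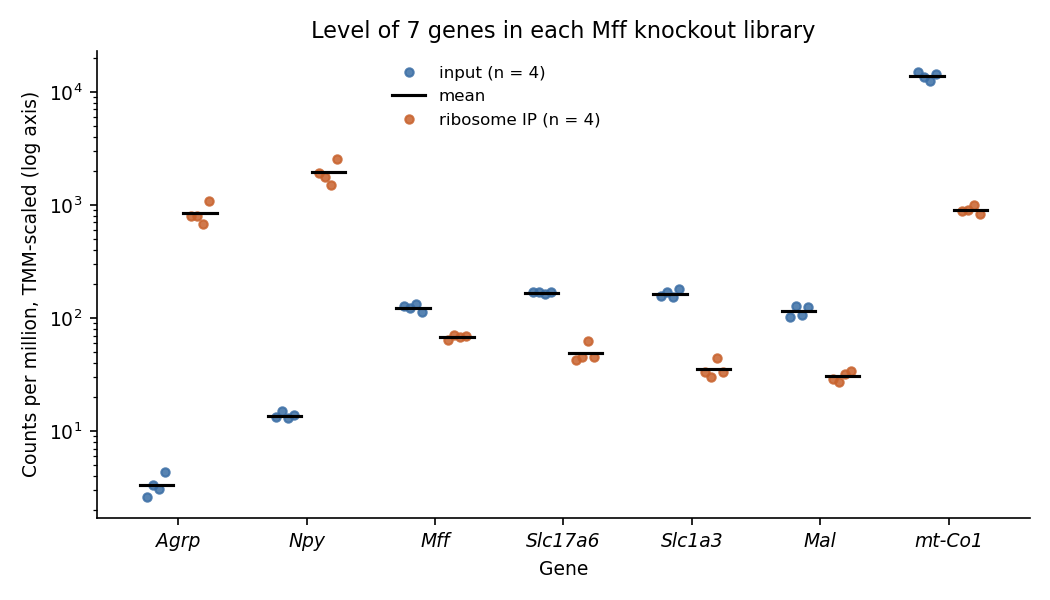
CPM (log axis, TMM-scaled) of 7 genes in each input library and each IP library of the Mff knockout, with black lines at the mean of the 4 libraries. Agrp and Npy lie higher in every IP library than in every input library, while Mff, Slc17a6, Slc1a3, Mal and mt-Co1 lie lower.

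Of 12 AgRP neuron markers, 11 were higher in IP and 1 was not past the threshold, and adjusted over the list alone 11 were higher and 1 was lower. The list's median log2 fold change was 3.76 (camera adjusted p = 7.12e-09, and adjusted p = 0.099 with an estimated correlation). Beyond Agrp, Npy, Mc3r and Acvr1c these were the protease gene Corin (5.61 ± 0.39), the homeobox gene Otp (3.90 ± 0.10), the ghrelin receptor gene Ghsr (3.62 ± 0.21), the calcitonin receptor gene Calcr (3.52 ± 0.09), the somatostatin gene Sst (2.45 ± 0.16), the leptin receptor gene Lepr (2.30 ± 0.24) and Asb4 (1.98 ± 0.11). Gpr83 had a log2 fold change of -0.45 ± 0.18 (adjusted p = 0.0681). Gpr83 passed the threshold as lower with RLE factors (adjusted p = 0.0493), upper quartile factors (0.0246), the filter of 1 CPM in 4 libraries (0.0494), DESeq2 (0.0314), limma-voom (0.0359, or 0.0461 with variance weights) and without IP replicate 2 (0.0173). Genes of GABAergic neurons split. The vesicular GABA transporter gene Slc32a1 was higher (1.21 ± 0.13), as was Gad1 (0.42 ± 0.14), whereas the developmental transcription factor gene Dlx1 was lower (-1.98 ± 0.18). In all, 2 of 10 members were higher and 6 lower, with the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.0673). Gad1 lost its call with upper quartile factors (0.29, adjusted p = 0.114), in limma-voom with variance weights (0.0793) and without input replicate 3 (0.0738) or 4 (0.0739) or IP replicate 1 (0.0737), 2 (0.0752) or 4 (0.0652). The list was called lower with the filter of 1 CPM in 4 libraries (adjusted p = 0.0435) and by fry (7.76e-05).

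Genes of insulin, leptin and nutrient sensing were higher as a list, with a median of 0.65 (camera adjusted p = 0.000953, and adjusted p = 0.099 with an estimated correlation). Of 27 members 15 were higher, 3 lower and 9 not past the threshold, and adjusted over the list alone 16 were higher and 3 lower. The list shares Lepr, Ghsr and Mc3r with the AgRP markers. The insulin receptor substrate gene Irs4 rose from 127 ± 5.8 to 1118 ± 135 CPM (log2 fold change 3.14 ± 0.09), whereas the growth kinase gene Mtor was lower (-1.04 ± 0.10). The receptor gene Igf1r was lower too (-0.83 ± 0.24), a call that ended without input replicate 4 (-0.76, adjusted p = 0.0574) and with GC and length offsets (-0.48, 0.134).

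Marker lists of glial and vascular cells were lower in IP. All 13 measured astrocyte markers were lower, also adjusted over the list alone, with a median of -1.68 (camera adjusted p = 1.49e-07, and adjusted p = 0.148 with an estimated correlation). They included the glutamate transporter gene Slc1a3 (-2.22 ± 0.12) and Aldoc (-1.58 ± 0.08). All 14 oligodendrocyte markers were lower, also adjusted over the list alone, with a median of -1.76 (adjusted p = 5.24e-08, and adjusted p = 0.108 with an estimated correlation), among them the myelin genes Mal (-1.91 ± 0.10) and Ermn (-2.49 ± 0.16). Of 10 oligodendrocyte precursor markers 8 were lower and 0 higher, in both adjustments, with a median of -1.89 (adjusted p = 0.000207, and adjusted p = 0.0875 with an estimated correlation). The growth factor receptor gene Pdgfra (-2.02 ± 0.19) and Olig1 (-1.80 ± 0.17) were 2 of these. Of 13 microglia markers 10 were lower in both adjustments, with a median of -1.84 (adjusted p = 0.000142, and adjusted p = 0.099 with an estimated correlation), including the protease gene Ctss (-1.86 ± 0.25) and the chemokine receptor gene Cx3cr1 (-1.96 ± 0.31). Of 21 vascular markers 8 were lower and 13 not past the threshold, in both adjustments, with a median of -1.03 (adjusted p = 0.00634, and adjusted p = 0.108 with an estimated correlation). The pericyte genes Rgs5 (-1.41 ± 0.33) and Pdgfrb (-2.00 ± 0.48) fell.

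Of 15 tanycyte and ependymal markers 6 were lower in both adjustments, including Gpr50 (-1.80 ± 0.29) and the deiodinase gene Dio2 (-1.29 ± 0.24), with a list median of -1.29 (camera adjusted p = 0.043, and adjusted p = 0.114 with an estimated correlation). This list lost its call with upper quartile factors (adjusted p = 0.0731), with no gene filter (0.0564), and without input replicate 3 (0.0536), IP replicate 3 (0.0623) or IP replicate 4 (0.0694). Pituitary markers were not called as a list (median -1.77, adjusted p = 0.136), with 3 of 5 measured members lower in both adjustments, among them Cga (-1.77 ± 0.44), which lost its call in limma-voom with variance weights (adjusted p = 0.0573). The list was called lower by fry (adjusted p = 0.00463) and with offsets and the replicate block (0.036). Erythrocyte genes were not called either (median -0.82, adjusted p = 0.102), with 2 of 5 members lower in both adjustments. They were called lower by fry (adjusted p = 0.0158), with the replicate block (median -0.84, 0.0445), with GC and length offsets (-1.36, 0.0076) and with offsets and block (-1.60, 0.00447).

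Of 18 markers of other arcuate neurons 15 were lower and 0 higher, in both adjustments, with a median of -1.39 (camera adjusted p = 2.42e-05, and adjusted p = 0.0875 with an estimated correlation). Slc18a2, the vesicular monoamine transporter gene, fell by 1.85 on the log2 scale (SE 0.17). Pomc, the melanocortin precursor gene of a neighbouring arcuate cell type, was chosen after its value was seen and had a log2 fold change of -0.93 ± 0.19. Pomc stood at -1.47 with GC and length offsets. Of 10 ventromedial and glutamatergic markers 7 were lower in both adjustments, with a median of -1.59 (adjusted p = 0.0032, and adjusted p = 0.144 with an estimated correlation), including the vesicular glutamate transporter gene Slc17a6 (-1.77 ± 0.12) and Fezf1 (-1.81 ± 0.16). Of 14 markers of neurons in other hypothalamic nuclei 10 were lower, and 11 adjusted over the list alone, with a median of -1.75 (adjusted p = 5.84e-05, and adjusted p = 0.108 with an estimated correlation). The melanin-concentrating hormone gene Pmch (-1.86 ± 0.14) and the orexin gene Hcrt (-1.89 ± 0.15, or -2.86 with offsets and the replicate block) were among them.

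**Figure D2:**
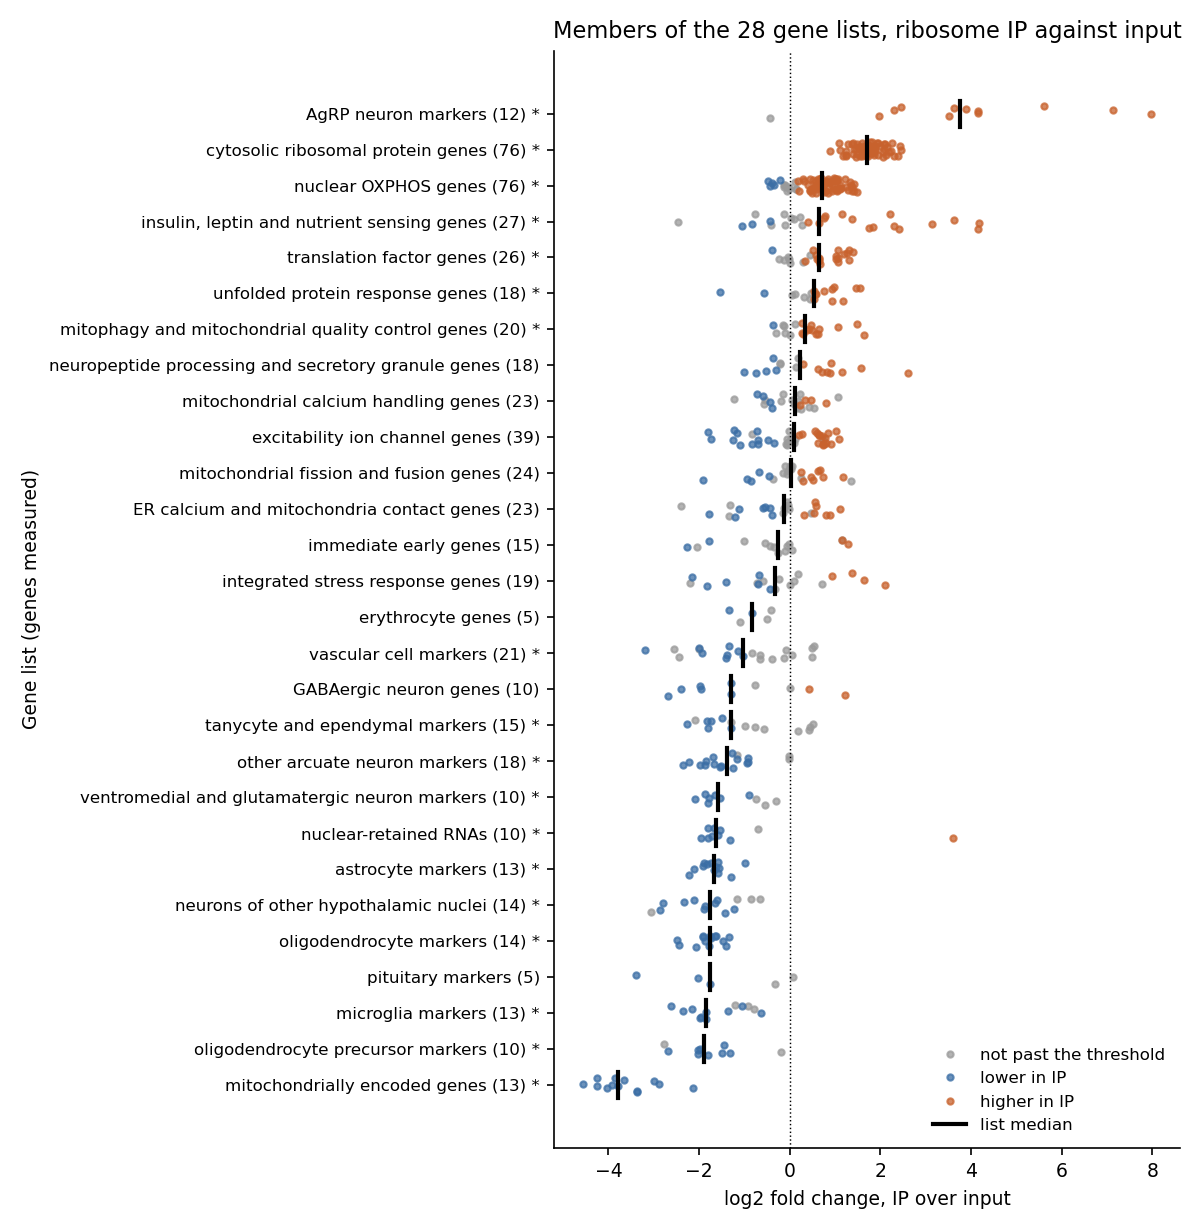
Log2 fold change of IP over input for each measured member of the 28 gene lists (points, coloured by the edgeR call) with the list median as a black bar; an asterisk marks lists called by camera with the preset correlation. AgRP neuron markers have the highest median (3.76) and mitochondrially encoded genes the lowest (-3.78).

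Transcripts encoded by the mitochondrial genome showed the largest depletion among the lists. The tagged RpL10a is counted here among the cytosolic ribosomal proteins, so this depletion is not read as a change in mitochondria. All 13 protein-coding mitochondrial genes were lower in IP, also adjusted over the list alone, with a median log2 fold change of -3.78 (camera adjusted p = 1.74e-10, and adjusted p = 0.099 with an estimated correlation). The cytochrome oxidase genes mt-Co3, mt-Co2 and mt-Co1 were at -4.56 ± 0.23, -4.03 ± 0.12 and -3.93 ± 0.08. The ATP synthase genes mt-Atp8 and mt-Atp6 were at -4.26 ± 0.16 and -4.25 ± 0.10, and the cytochrome b gene mt-Cytb at -3.85 ± 0.11. The complex I genes mt-Nd4, mt-Nd2, mt-Nd1 and mt-Nd4l were at -3.78 ± 0.16, -3.66 ± 0.14, -3.38 ± 0.09 and -3.37 ± 0.20. The mitochondrial ribosomal RNA genes mt-Rnr2 (-4.55 ± 0.10) and mt-Rnr1 (-4.02 ± 0.09) and the transfer RNA gene mt-Ts1 (-3.58 ± 0.12) fell alike. The remaining gene of the 14 most depleted was Rn7s1, a signal recognition particle RNA gene, at -3.66 ± 1.07 (adjusted p = 0.0159). Rn7s1 stood at 13.3, 0, 0 and 8.67 CPM in IP replicates 1 to 4, so the size of its change is uncertain. Rn7s1 was not called by DESeq2 (adjusted p = 0.128) and stood at -8.27 in limma-voom and at -6.17 with offsets and the replicate block. Nuclear copies of mitochondrial sequences can share reads with these genes.

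As shares of a library's counts, the 13 mitochondrial protein-coding genes went from 3.85% ± 0.15 in input to 0.337% ± 0.090 in IP (SD, n = 4). The 76 cytosolic ribosomal protein genes went from 1.41% ± 0.11 to 5.02% ± 0.24. The 10 genes with the highest mean share, led by the 18S ribosomal RNA gene Rn18s-rs5 and mt-Rnr2, took 41.5% ± 1.7 of input counts and 29.4% ± 1.6 of IP counts. Their members moved both ways. The share of mt-Rnr2 was 15.7% to 17.8% in input and 0.643% to 0.919% in IP. That of Rn18s-rs5 was 7.29% to 11.3% in input and 11.3% to 23.8% in IP. The 382 ribosomal RNA features, mitochondrial ones and genes added by name included, took 38.4% ± 1.4 of input counts and 28.8% ± 1.7 of IP counts. Of the genes added by name, Yam1 took 0.900% to 2.08% of input counts and 3.77% to 12.4% of IP counts. Lars2 took 0.334% to 0.521% and 1.13% to 1.55%. The 5 erythrocyte genes took 0.0217% ± 0.0046 and 0.0134% ± 0.0035. Each difference had an exact permutation p of 0.0286 (n = 4 per fraction), the smallest possible, and the same value after adjustment over the 5 shares. The erythrocyte difference of -0.00831 percentage points missed 0.05 without input replicate 4 (-0.00631, exact p = 0.0571) and without IP replicate 1 (-0.00667, exact p = 0.0857), 2 (-0.00877), 3 (-0.00935) or 4 (-0.00844), the last 3 each with an exact p of 0.0571 (n = 3 against 4 libraries). The mitochondrial and ribosomal protein shares kept p-values under 0.05 without any 1 library.

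**Figure D3:**
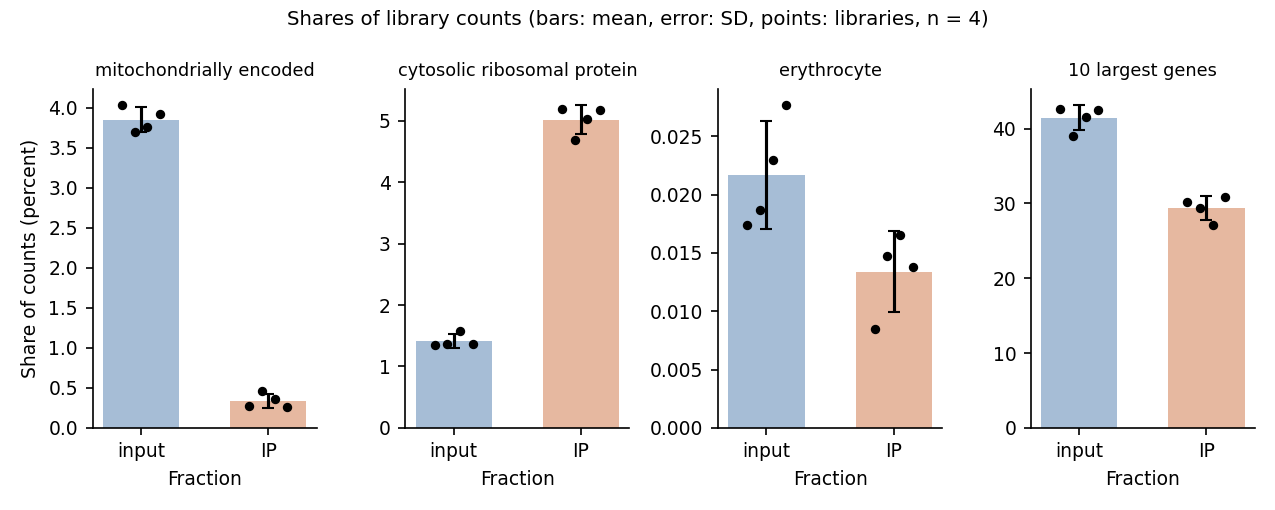
Percent of each library's estimated counts taken by 4 gene groups in input and IP, with bars at the mean, error bars of 1 SD and a point per library (n = 4 per fraction). Mitochondrially encoded genes fall from 3.85% to 0.337% and cytosolic ribosomal protein genes rise from 1.41% to 5.02%.

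Genes of mitochondrial fission and fusion moved in both directions. Of 24 measured genes 8 were higher, 5 lower and 11 not past the threshold, with the same numbers higher and lower adjusted over the list alone. For this list and those below, the shares over all tested genes were 24.5% higher and 20.9% lower. The list was not called, with a median of 0.02 that ran from -0.11 with upper quartile factors to 0.14 with GC and length offsets (camera adjusted p = 0.563). Besides Mff, the lower genes were the actin regulators Inf2 (-1.90 ± 0.39) and Spire1 (-0.95 ± 0.10) and the fusion GTPase genes Mfn1 (-0.67 ± 0.15) and Opa1 (-0.45 ± 0.07). The higher genes included the phosphatase gene Pgam5 (1.18 ± 0.19), the fission adaptor gene Fis1 (0.72 ± 0.06), the fission regulator genes Mtfr1 (0.66 ± 0.14) and Mtfr1l (0.48 ± 0.07), and the second mitofusin gene, Mfn2 (0.30 ± 0.09). Dnm1l, the gene of the fission GTPase DRP1, had a log2 fold change of -0.06 ± 0.07 (adjusted p = 0.544), and the other DRP1 receptor genes Mief1 and Mief2 had -0.04 ± 0.21 and -0.11 ± 0.32, with either sign among the alternatives. With GC and length offsets Dnm1l was called higher (0.28), Opa1 was not called (-0.11, adjusted p = 0.187) and Fis1 stood at 0.18, where the replicate block added to the offsets ended its call (adjusted p = 0.0553). With upper quartile factors Mfn2 was not called (0.17, adjusted p = 0.139) and Dnm1l was called lower (-0.19).

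Genes of mitochondrial calcium handling were also mixed, with 4 of 23 higher, 4 lower and 15 not past the threshold, and the same numbers higher and lower adjusted over the list alone. The list was not called (median 0.11, running from -0.02 with upper quartile factors to 0.21 with library totals alone, camera adjusted p = 0.691). Within the calcium uniporter complex, the regulator genes Smdt1 (0.80 ± 0.07), Micu2 (0.47 ± 0.14) and Micu3 (0.23 ± 0.07) were higher. The pore gene Mcu had -0.57 ± 0.27 (adjusted p = 0.116) and passed the threshold with the replicate block (-0.67, adjusted p = 0.048), in limma-voom with variance weights (-0.63, 0.0484) and without IP replicate 3 (-0.82, 0.018), while without IP replicate 1 it stood at -0.34. The calcium-activated carrier gene Slc25a12 was higher (0.33 ± 0.08), and Slc25a23 (-0.73 ± 0.12), Ppif (-0.60 ± 0.16), Ghitm (-0.44 ± 0.07) and Letm1 (-0.39 ± 0.12) were lower. Letm1 lost its call without input replicate 2 (-0.34, adjusted p = 0.0636), with library totals alone (-0.29) and with GC and length offsets (-0.29). With these offsets Smdt1 stood at -0.00 (adjusted p = 0.987), Ghitm at -0.21, Micu3 at 0.86 and Slc25a12 at 0.63. Upper quartile factors ended the calls of Micu2, Micu3 and Slc25a12 (adjusted p = 0.0691, 0.297 and 0.0594).

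**Figure D4:**
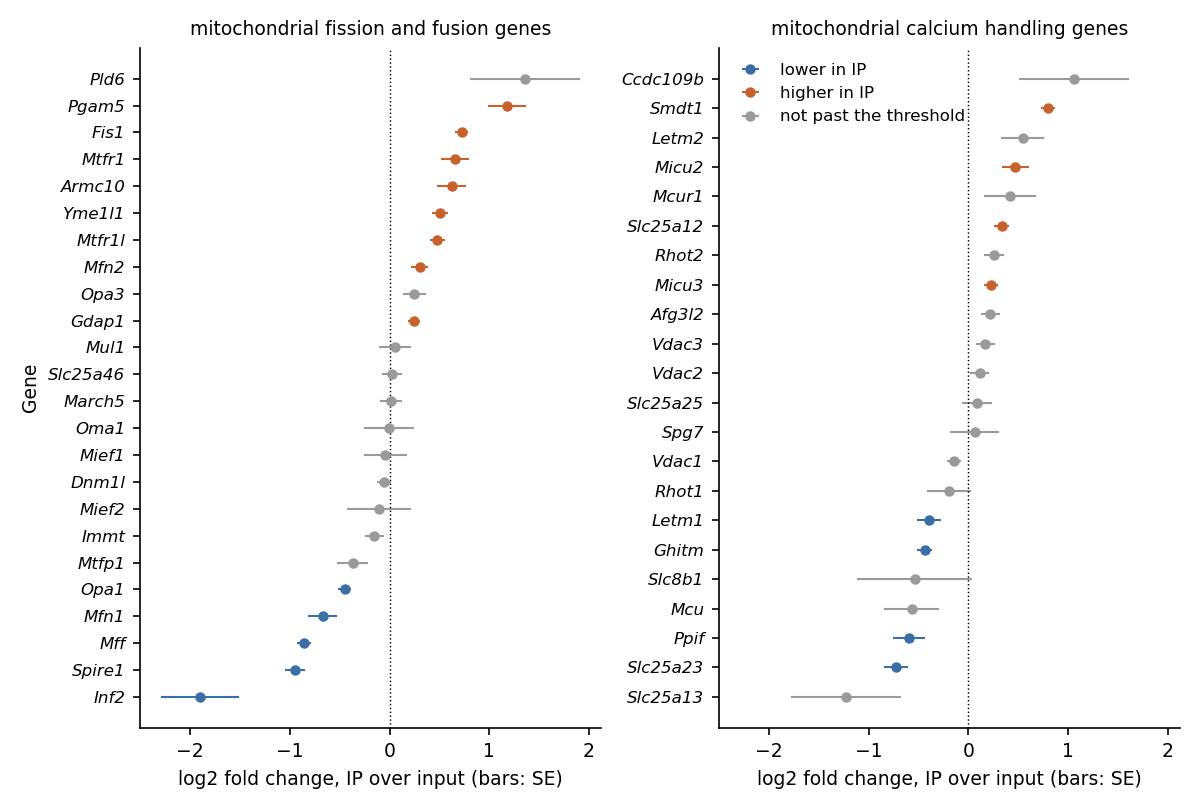
Log2 fold change of IP over input, with SE bars from edgeR, for the 24 measured mitochondrial fission and fusion genes (left) and 22 of the mitochondrial calcium handling genes (right), coloured by call (n = 4 libraries per fraction). Members lie on both sides of 0 in each list, and Mff is at -0.86.

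Of 23 genes of endoplasmic reticulum calcium and mitochondrial contacts 7 were higher and 7 lower, in both adjustments, and the list was not called (median -0.12, running from -0.26 with upper quartile factors to -0.01 with GC and length offsets, camera adjusted p = 0.553). The tether gene Vapb (0.57 ± 0.06) and Tmx1 (0.89 ± 0.10) were higher. Pacs2 (-0.58 ± 0.09) and the calcium release channel gene Ryr2 (-1.11 ± 0.13, or -0.66 with GC and length offsets) were lower.

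Nuclear genes of oxidative phosphorylation (OXPHOS) were higher in IP as a list. Of 76 members 62 were higher, 5 lower and 9 not past the threshold, with the same numbers higher and lower adjusted over the list alone, and the median was 0.72 (camera adjusted p = 1.56e-14, and adjusted p = 0.099 with an estimated correlation). The increases included Ndufv3 of complex I (1.49 ± 0.08) and Atp5j2 of the ATP synthase (1.30 ± 0.07), while Atp5b (-0.43 ± 0.07) and Ndufs1 (-0.47 ± 0.10) were lower. Log2 fold changes followed transcript length over 8450 genes of at least 10 CPM (Spearman rho -0.41, and 0.22 with GC content). These correlations are across genes, which are not independent replicates. The 20% of genes with the shortest transcripts (median length 1353 nt) had a median of 0.61 and the 20% with the longest (7534 nt) -0.19. With GC and length offsets the median of the OXPHOS list was 0.13 (adjusted p = 0.017), and Atp5j2 stood at 0.84.

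**Figure D5:**
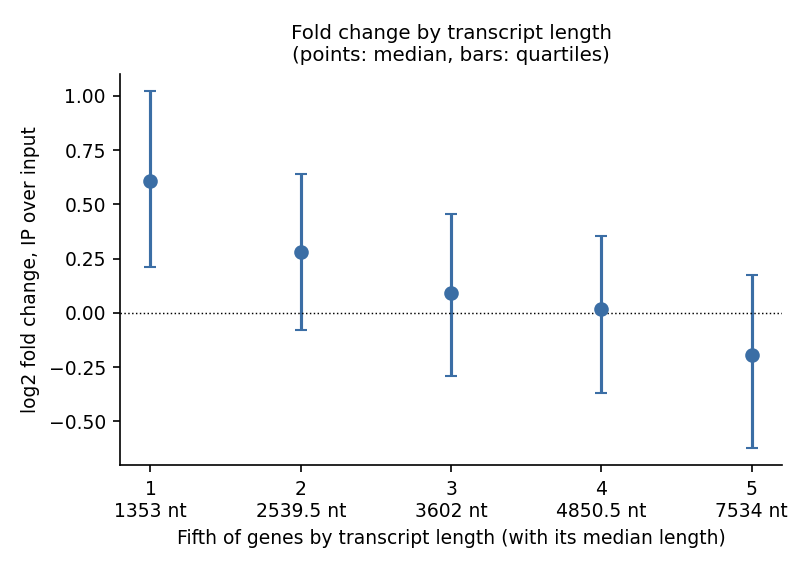
Median log2 fold change of IP over input (points) with quartiles (bars) for 5 groups of 1690 genes each, ordered by annotated transcript length, among genes with a mean of at least 10 CPM. The median falls from 0.61 in the group with the shortest transcripts to -0.19 in that with the longest.

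All 76 cytosolic ribosomal protein genes were higher in IP, also adjusted over the list alone, with a median of 1.70 (camera adjusted p = 8.74e-38, and adjusted p = 0.114 with an estimated correlation), among them Rpl13a (2.15 ± 0.07) and Rps27a (2.23 ± 0.08). Translation factor genes were higher as a list, with a median of 0.64 (adjusted p = 2e-06, and adjusted p = 0.099 with an estimated correlation). Of 26 members 18 were higher and 1 lower, and adjusted over the list alone 19 were higher and 2 lower. The start-site factor gene Eif1 (1.20 ± 0.06) and Eif3f (1.40 ± 0.07) were higher. Eif5b was lower (-0.40 ± 0.09), a call that ended with GC and length offsets (-0.01, adjusted p = 0.927). Among 20 genes of mitophagy and mitochondrial quality control 13 were higher and 1 lower, in both adjustments, with a median of 0.35, or 0.21 with upper quartile factors (adjusted p = 0.00634, and adjusted p = 0.099 with an estimated correlation). The chaperonin gene Hspe1 was higher (1.48 ± 0.13, or 0.85 with GC and length offsets). The lower member, Trap1 (-0.36 ± 0.13, adjusted p = 0.0383), lost its call with library totals alone (0.128) and in 6 of the 8 fits with a library left out.

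Unfolded protein response genes were higher as a list, with a median of 0.54 (camera adjusted p = 0.0021, and adjusted p = 0.278 with an estimated correlation). Of 18 members 11 were higher and 2 lower, and adjusted over the list alone 13 were higher and 2 lower. The chaperone gene Hyou1 (1.18 ± 0.08) and Manf (1.47 ± 0.16) were higher, and Edem1 was lower (-1.54 ± 0.34). The other lower member, Atf6 (-0.58 ± 0.13), lost its call with GC and length offsets (-0.25, adjusted p = 0.153). Integrated stress response genes were not called as a list (median -0.33, adjusted p = 0.275, or 0.00117 by fry), with 4 of 19 higher and 6 lower, or 5 and 7 adjusted over the list alone. The transcription factor genes Atf5 (1.38 ± 0.16) and Atf3 (2.10 ± 0.50) were higher, and the serine synthesis genes Phgdh (-2.17 ± 0.16) and Psat1 (-1.41 ± 0.11) were lower. Immediate early genes were not called (median -0.27, running from -1.01 without IP replicate 3 to -0.06 without input replicate 3, adjusted p = 0.39), with 2 of 15 higher and 2 lower in both adjustments, including Jun (1.28 ± 0.12), Arc (-2.26 ± 0.24) and Fosb (-1.78 ± 0.45). The other higher member, Junb (1.16 ± 0.36), lost its call without input replicate 1 (adjusted p = 0.0521), 2 (0.059) or 4 (0.0617) and with GC and length offsets (0.072), and stood at 0.76 without IP replicate 3.

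Genes of neuropeptide processing and secretory granules were not called as a list (median 0.24, or 0.10 with upper quartile factors, camera adjusted p = 0.114), although 9 of 18 were higher and 5 lower in both adjustments. The list was called higher with no gene filter (adjusted p = 0.0155) and by fry (0.000829). Pcsk1n, which encodes a convertase inhibitor, rose from 154 ± 10 to 935 ± 85 CPM (log2 fold change 2.60 ± 0.08), and the granule membrane gene Ptprn was higher by 1.58 ± 0.10. The carboxypeptidase gene Cpe (-0.74 ± 0.07) and the synaptic gene Snap25 (-1.01 ± 0.07) were lower. Of 39 ion channel genes 17 were higher and 12 lower, in both adjustments, and the list was not called (adjusted p = 0.521). Its median was 0.09, its mean -0.01, and the median ran from -0.04 with upper quartile factors to 0.25 with GC and length offsets. The list was called with offsets and the replicate block (median 0.23, adjusted p = 0.0435). The glutamate receptor gene Gria4 (1.08 ± 0.11) and the potassium channel gene Kcnj3 (0.74 ± 0.09) were higher, and Gria3 (-1.26 ± 0.08) and the sodium channel gene Scn8a (-1.10 ± 0.11) were lower. Of 10 nuclear-retained RNAs 8 were lower and 1 higher, in both adjustments, with a median of -1.63 (adjusted p = 0.00338, and adjusted p = 0.193 with an estimated correlation). Snhg11 (-1.81 ± 0.16) and Neat1 (-1.67 ± 0.15, or -1.09 with GC and length offsets) were lower, and the higher one was Gm26917 (3.61 ± 0.33). Gm26917 is also among the 382 ribosomal RNA features left out in an alternative, where it was added by name. Its counts may hold reads of ribosomal RNA, which was not tested.

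Over the whole transcriptome, 7716 of 17000 tested genes differed between IP and input, 4171 higher and 3545 lower. A change of at least 2-fold was reached by 3514 of these, 1423 higher and 2091 lower. With upper quartile factors the split was 3342 higher and 4384 lower, since this scaling moved the median log2 fold change of all tested genes from -0.01 to -0.15. In 8177 genes (48.1%) the 4 IP libraries did not overlap the 4 input libraries, against 2.86% by chance. Camera called 18 of the 28 lists, 7 higher and 11 lower. With an estimated correlation 0 lists were called by camera, 12 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0875, while fry called 23.

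The IP libraries varied more among themselves than the input libraries. Pearson correlations of log2 CPM, which are across genes, were 0.987 to 0.988 within input, 0.922 to 0.945 within IP and 0.896 to 0.914 between fractions. The biological coefficient of variation was 0.104 within input and 0.52 within IP, and 0.0734 and 0.172 over genes of at least 10 CPM. The first principal component (55.2% of variance) separated the fractions, and the second (16.7%) set IP replicate 3 apart from the other IP libraries. Without IP replicate 3 the count of genes past the threshold was 8738, with 4508 higher and 4230 lower.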

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

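Among 270 groups of 4 libraries examined, 15 held a library whose gap to its nearest neighbour exceeded Dixon's 95% critical value for 4 values, against 13.5 expected at 1 in 20. The tests of OXPHOS genes against scaling and of Mff against carry-over and deletion were chosen only after the result was seen.

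In IP replicate 4, Mc3r stood high at 42.37 CPM (others 19.3 to 23.2), as did Acvr1c at 262.7 CPM (others 193.7 to 198.9), Tbx3os2 at 34.52 CPM (others 26.2 to 26.9) and Arc at 3.621 CPM (others 1.90 to 2.12). In IP replicate 3, Slc17a6 stood high at 63.02 CPM (others 42.9 to 44.9) and Junb at 9.724 CPM (others 3.804 to 4.651), while Pcsk1n stood low at 806.9 CPM (others 973.4 to 980.0). Junb is among the genes whose call ended in some fits with a library left out. Ermn stood high in IP replicate 2 at 27.49 CPM (others 16.5 to 18.0).

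Among inputs, replicate 3 held 1.583 CPM of Tbx3os2 (others 0.674 to 0.819), 162.8 CPM of Slc17a6 (others 168.4 to 169.5), 77.06 CPM of Hcrt (others 90.9 to 91.8) and 1.574% of counts in ribosomal protein genes (others 1.35% to 1.37%). Input replicate 2 held 2128 CPM of mt-Co2 (others 2607 to 2690) and 87.21 CPM of Mfn2 (others 74.2 to 74.5). Input replicate 4 held 17.15 CPM of Igf1r (others 14.6 to 14.8), and without it the call of Igf1r ended (adjusted p = 0.0574).

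A first pattern is the higher level of nuclear OXPHOS genes in IP (median log2 fold change 0.72). Scaling of libraries with different ribosomal RNA content was examined with 4 other scalings, and the list median was still 0.587 under the lowest. The choice among these scalings therefore does not account for the pattern. They put the median of all tested genes only between -0.15 and 0.09, so the list could hardly have reached the bound of 0.1. A larger scaling error was not tested. A trend with transcript length and GC content stays partly open. Offsets that remove such a trend took the list median to 0.1259 (adjusted p = 0.017), between the bounds of 0.1 and 0.2 set for that test, with 31 members higher, 12 lower and 33 not past the threshold. The trend could therefore account for much of the pattern, but the offsets also remove any biological difference that follows length, and no biological explanation was tested.

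A second pattern is Lars2, a mitochondrial leucyl-tRNA synthetase gene chosen after its value was seen, which took 0.334% to 0.521% of input counts and 1.13% to 1.55% of IP counts (log2 fold change 1.64 ± 0.16). A candidate explanation is reads of ribosomal RNA assigned to Lars2, whose mouse locus is known to hold a stretch resembling ribosomal RNA. The median of the other 16 mitochondrial aminoacyl-tRNA synthetase genes was -0.01511 (range -1.49 to 0.89), as that explanation needs. Against 18S ribosomal RNA as the lone source, Lars2 counts per 100 counts of Rn18s-rs5 were 4.33 to 5.09 in input and 6.31 to 10.0 in IP. The log2 fold change of Lars2 lay between those of Rn18s-rs5 (1.02 ± 0.22) and Yam1 (2.04 ± 0.35). Lars2 and Yam1 were themselves placed among the ribosomal RNA features by name, so this position is no separate support. The 28S ribosomal RNA was not measured here, and no biological explanation was tested.

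Another pattern is the lower level of Mff in IP (-0.86 ± 0.07). The length and GC trend is argued against, since Mff stayed at -0.8069 (adjusted p = 3.74e-06) with offsets. Carry-over of tissue RNA as the source of all Mff counts in IP stays open, because Mff lay -0.03353 from the highest median among 11 lists of other cell types, that of 5 erythrocyte genes (-0.82). Mff lay above the other 10 medians by 0.17 to 1.04, and above all 11 by at least 0.27 with offsets, where erythrocyte genes stood at -1.36. Single genes scatter around a list median, with an SD of 0.454 over 40 glial markers, so the smaller of these gaps cannot decide. Deletion in AgRP neurons cannot be told apart from a low native level in these cells, since no control genotype is analysed here, and Mff stood at percentile 6.7 among 1000 genes nearest in input level and transcript length.

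Whether chance could give these counts was examined over all 35 splits of the 8 libraries into 4 and 4. For genes past the threshold (7716), higher (4171), lower (3545) and 2-fold (3514), only 1 split, the real one, reached the value. A share of 1 in 35 lies under the bound set beforehand and argues against chance. It is also the smallest share these splits can give, so chance is not excluded. The highest count among the other splits was 0 genes by edgeR, where 40 to 1082 genes had an unadjusted p under 0.05. The other splits leave the difference between fractions in the residual spread, so their 0 is not the number of genes chance would call. No other tool was run on the splits. For the 18 gene lists called, 7 splits including the real one gave as many, the highest other giving 21, so chance is not excluded by that count. Splits with 3 libraries of a fraction on each side called 12 to 21 lists and splits with 2 of each called 0 to 3, which points to the structure of the samples, since the former still carry part of the contrast between fractions.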

How the results depend on the processing

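The tests with ribosomal RNA features left out, limma-voom with 1 variance weight per fraction and list tests with GC and length offsets were chosen after seeing the data. Mff stayed lower and Agrp higher, past the threshold, in every alternative run. Counts of genes past the threshold stayed within 1.5 times of 7716, from 6523 without input replicate 1 to 8738 without IP replicate 3, and were 8372 by DESeq2 and 8680 by limma-voom. Genes at least 2-fold lower were 2091, and 3159 with no gene filter, which tests more low genes (28376 in all) and moved the median log2 fold change of all tested genes to -0.26. With an estimated correlation, camera called 0 lists (0 higher, 0 lower), also among lists whose estimated correlation lay under the preset one. Other arcuate neuron markers (estimated correlation 0.0034) went from an adjusted p of 2.42e-05 to 0.0875. Oligodendrocyte precursor markers (-0.0029) went from 0.000207 to 0.0875. This argues against a stronger correlation between genes as the reason in such lists. The estimated version also uses the few residual degrees of freedom of the libraries, which raises p by itself. How much each of these matters in the other lists was not tested. Smdt1 turned from 0.80 to -0.0014 and Dnm1l from -0.06 to 0.282 with GC and length offsets (no block), and to -0.000674 and 0.283 with offsets and the replicate block. Whether length or GC content was the cause was not tested separately. The erythrocyte share difference ranged from -0.00974 to -0.00631 percentage points when each library was left out, and leaving out a library also leaves fewer arrangements.

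Replicate numbers are shared by IP and input, but deviations of same-numbered libraries correlated at 0.048 to 0.084, under 0.1, so the numbers were not taken to pair them. Each IP library still correlated best with the input of its own number, a hint from the data and not from the design. If the numbers do mark pairs, the exact permutation tests and the splits ignore that pairing, since they exchange libraries freely. Exchange within pairs alone would allow fewer arrangements, and the smallest possible exact p would then lie above 0.05. With the replicate block 7592 genes passed the threshold, Mff stood at -0.856 and 19 lists were called. Thinning all libraries to the smallest total left 7654 genes past the threshold.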

Other observations

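The tests of imprinted genes and of STAT feedback genes were chosen after some of their members had been seen, and all genes in this part were chosen after their values were seen.

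Among other genes higher in IP, the homeobox gene Bsx had a log2 fold change of 3.90 ± 0.20 (SE, n = 4 per fraction), Six6 2.42 ± 0.14 and Isl1 2.15 ± 0.14. The growth hormone receptor gene Ghr rose from 13.4 to 167 CPM (3.64 ± 0.15), the GABA receptor subunit gene Gabre from 17.0 to 182 CPM (3.42 ± 0.11), and the potassium channel gene Kcnj5 from 15.5 to 96.6 CPM (2.64 ± 0.13). The autophagy gene Atg7 was higher by 2.96 ± 0.19. Each of these passed the edgeR threshold. On the depleted side, Nme7 fell by 3.09, the glial secreted protein gene Sparcl1 by 2.28 and the apolipoprotein gene Apoe by 2.03 on the log2 scale.

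Imprinted genes, which are expressed from the copy of a single parent, recurred among the enriched genes, with Plagl1 at 2.89 ± 0.08, Dlk1 at 2.85 ± 0.08 and Magel2 at 2.42 ± 0.13. The hypothesis that imprinted genes as a set are higher in IP was tested on a list of 33 measured genes, 8 of which had been seen beforehand. In the whole list 18 were higher, 4 lower and 11 not past the threshold (camera adjusted p = 2.02e-05 over the 2 lists of this part, and adjusted p = 0.0315 with an estimated correlation). Among the 25 not seen beforehand 12 were higher and 3 lower, with a median of 0.335 (camera adjusted p = 0.00329), including Peg10 (1.78 ± 0.12) and Ndn (1.33 ± 0.07). The estimated correlation was not run on these 25, and they come from the same libraries, so this is no independent support. Against the direction were Nnat (-0.66 ± 0.17) and Igf2 (-1.07 ± 0.37). The list shares Calcr and Asb4 with the AgRP markers. The set may be enriched in ribosome-bound RNA of these neurons, but input mixes all cells, so other arcuate neurons could show the same.

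Genes of growth hormone and STAT feedback also drew attention, with Ghr, Socs3 (2.41 ± 0.42), Cish (2.31 ± 0.19), Socs2 (2.12 ± 0.18) and Stat3 (1.84 ± 0.09) higher in IP. For the whole list of 12 camera gave an adjusted p of 0.00805, but this rests on the 5 members seen beforehand. The other 7 had a median of -0.04665 (camera adjusted p = 0.855), with 2 higher and 1 lower, which met the rule set beforehand for no shift. They ran from -0.71 (Bcl6) to 2.43 (Socs1). A shift of the set beyond the members seen was not found. These 7 cannot decide against one, since the 5 left out were noticed because they were high.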
